A study of Sus scrofa with 8 samples.

How the data were processed

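Messenger RNA of heart tissue was measured by RNA sequencing in 8 wild-type miniature pig samples, 3 given vehicle and 5 given doxorubicin. Per the labels' protocols, total RNA was purified on silica columns and turned into sequencing libraries with a SMARTER mRNA kit. The authors deposited a table of raw counts per gene, with 1 column for each sample, and the columns were matched to the samples by the titles in the labels. Values were whole numbers with a different total in each library, so no normalization preceded deposit as far as the values show. The aligner, the counting tool, their versions, and whether counting used the strand are not given in the sources used here. Reads of overlapping or antisense genes can therefore not be told apart, and genes with near-identical copies are uncertain. The dose, the schedule, the age and the sex of the animals are likewise not given in the sources used here.

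The table listed 31014 genes, of which 655 were unannotated loci assembled from the reads, as their identifiers in the deposited table show. Identifiers of 30335 genes matched a RefSeq table of the pig assembly Sscrofa11.1, and all 30335 had the same start and end there, so coordinates are printed on that assembly. Gene names were taken from the deposited table and from that RefSeq table. Library totals ran from 16105242 to 18267178 counts. Pairs of libraries within a group differed by 18.5 to 308 times what sampling noise gives (chi-square over its degrees of freedom), so no library was counted as a copy of another.

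Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14938, and libraries were scaled by TMM. Doxorubicin was compared with vehicle by the robust quasi-likelihood test with treatment as the only term. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and tests were two-sided. Standard errors (SE) are on the log2 scale, from the fold change and its F statistic. CPM are counts scaled by TMM-adjusted library size, given as mean ± SD over 3 vehicle and 5 doxorubicin libraries. The bound for a gene with 0 reads in a group was taken against a floor of 3 counts summed over that group's libraries. The floor was not TMM-scaled and covers counting error only. The fit was tested on simulated counts with 200 changed genes among the 14938, and 40 further genes shifted 1.5-fold for the list test. It recovered 2% of 50 genes changed 1.5-fold, 10% of 50 changed 2-fold, 80% of 50 changed 4-fold and 92% of 50 changed 8-fold. There were 8 false calls among 100. Far fewer genes passed there than in the data (100 against 3714), which made the adjusted threshold stricter. The recovered shares therefore do not give the power of the fit to the data.

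The design of each test, the alternatives, the gene lists, the cell type marker lists and the rule for named genes were fixed before the data were examined. The rule named 8 genes in any case (ESRRA, PPARGC1A, PPARA, TOP2B, CDKN1A, NPPA, NPPB and MYH7), the 10 higher and the 10 lower genes with the smallest p among genes with a symbol, a mean of 1 CPM or more and no overlap between the groups, and up to 4 members with the smallest p in each list described. Lists with 3 or more tested members were tested with camera at a preset correlation of 0.01, adjusted over all 58 lists (38 gene lists and 20 cell type lists). Here camera compares the members of a list with all other genes. Each list also has the count of its members past the gene-wise threshold, over all genes and adjusted over the list alone, camera with an estimated correlation, and fry, which asks whether the members move one way on balance without comparing them with other genes. Complex III had 2 members under their symbols here and was not tested by itself. Shares of counts were compared by exact permutation over all 56 splits of the 8 libraries into 3 and 5, where the smallest p is 0.0357. The mitochondrial, haemoglobin and 20 most abundant gene shares were planned. Those of COX1, of all unannotated loci and of an unannotated locus like COX1 were added. The adjusted p takes both kinds together.

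Alternatives were RLE factors, library size only, no filter, CPM above 1 in at least 3 libraries, normalization without mitochondrial, haemoglobin and the 20 most abundant genes, a 2-fold minimum, the replicate number as a block, DESeq2 1.42.0, limma 3.58.1 voom with quality weights, cameraPR, and leaving out each library in turn. Removal of each library's trend with gene density (protein-coding genes within 500 kb, lowess span 0.3) and with gene length was added after the data were seen. Each trend was taken on the deviation of each gene from its mean over the 8 libraries. Sex was not used as a term because Y-linked genes were read in all 8 libraries. Figures were drawn with matplotlib 3.10.9.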

Results

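Doxorubicin, an anthracycline used against cancer, is known to damage the heart, and the title of the series names the nuclear receptor ERRα (gene ESRRA) and mitochondrial metabolism in that setting. The samples compared here ask how the heart transcriptome of miniature pigs given doxorubicin (n = 5) differed from that of animals given vehicle (n = 3). Library totals were 16307586, 17195538 and 16105242 counts in vehicle 1 to 3, and 17442566, 18267178, 18200200, 18000404 and 18171443 counts in doxorubicin 1 to 5. The labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples. On the first principal component (58.2% of variance) the vehicle libraries lay between −70.8 and −62.6 and the doxorubicin libraries between −1.36 and 102. Doxorubicin 5 stood apart, with a mean correlation of 0.912 with its own group, against 0.941 to 0.956 for the other doxorubicin libraries and 0.974 to 0.977 for vehicle.

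**Figure D1:**
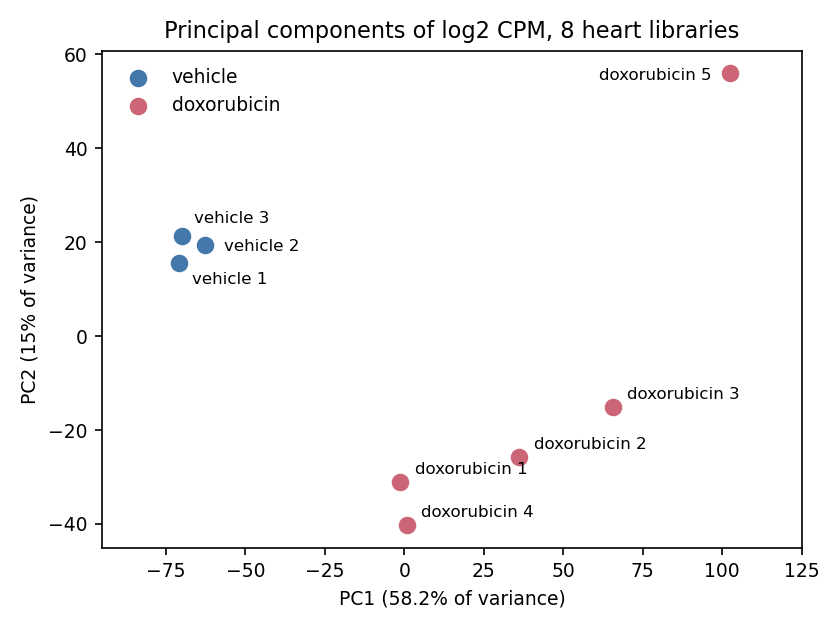
Principal components of log2 CPM in the 8 heart libraries, each point 1 library, with the share of variance on each axis. The 3 vehicle libraries lie together. The doxorubicin libraries spread along the first component, with 1 and 4 at −1.36 and 0.713 and 2, 3 and 5 at 36.1, 65.5 and 102. Doxorubicin 5 lies away from the other doxorubicin libraries.

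After doxorubicin, 10 of the 13 respiratory chain subunits encoded in mitochondrial DNA fell (median log2 fold change −1.27). Of 40 collagen and matrix genes 31 rose (median 2.87), and of 39 cell cycle genes 19 rose and 1 fell. CDKN1A, the p53-induced inhibitor of the cell cycle, rose 13.4-fold, from 11.8 ± 2.06 to 158 ± 71.7 CPM (SD, n = 3 and n = 5). ESRRA itself was at 161 ± 47.7 CPM in vehicle and 167 ± 54.9 CPM after doxorubicin, with a log2 fold change of 0.06 (SE 0.30) and an adjusted p of 0.907. By camera the mitochondrial DNA, matrix and cell cycle lists had adjusted p of 9.59e-08, 1.57e-11 and 9.21e-05, and none of the 3 passed with an estimated correlation (adjusted p = 0.675 with an estimated correlation for each).

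In all, 3714 of 14938 tested genes (24.9%) passed the threshold, 2033 higher and 1681 lower, and 6095 had an unadjusted p under 0.05. At least a 2-fold change was seen for 1885 of the called genes, 1389 higher and 496 lower. Most calls were protein-coding genes (3506), with 124 lncRNAs and 57 unannotated loci. Groups did not overlap for 3538 of the called genes and for 34.9% of all tested genes, where chance gives 3.57%. The balance of directions depended on the scaling. With library size only, 4592 genes passed, 4093 higher and 499 lower. That fit leaves out the TMM factors, which ran from 0.839 to 0.874 in vehicle and from 1.05 to 1.18 after doxorubicin. The median log2 fold change of all tested genes then moved by 0.357, to 0.378. List medians with library size only are to be read against that value. After each library's trend with gene density was removed 3182 passed, 1403 higher and 1779 lower. Leaving out vehicle 1, vehicle 2 or vehicle 3 left 649, 1969 or 712 calls. Of the 133 named genes that passed, 52 did so whichever single library was left out, and with library size only 24 lower calls among the named genes no longer passed.

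PPARGC1A, the coactivator of ERRα that drives mitochondrial biogenesis (chromosome 8, 17841844 to 18527953), had a log2 fold change of −0.60 (SE 0.31, adjusted p = 0.169), at 116 ± 16.5 CPM in vehicle and 76.7 ± 29.8 CPM after doxorubicin. PPARA, a receptor that controls fatty acid oxidation (chromosome 5, 3302755 to 3321091), had −0.31 (SE 0.67, adjusted p = 0.761). ESRRA lies on chromosome 2, 7803504 to 7812868; all 3 are protein-coding, and none of them passed the test. The sign of ESRRA turned without the density trend and without any 1 of vehicle 1, vehicle 3 and doxorubicin 1, 2 and 4, and that of PPARA with library size only. Among 20 ERR regulators, 0 rose, 5 fell and 15 did not pass (0 and 5 adjusted over the list alone), with a median log2 fold change of −0.39 and a list adjusted p of 0.0375. The smallest p among them belonged to TFB2M (−0.80, SE 0.16, adjusted p = 0.0109) and TFAM (−0.96, SE 0.20, adjusted p = 0.0125), which drive transcription of mitochondrial DNA. Next came GABPA (−0.46, SE 0.13, adjusted p = 0.0307), an activator of respiratory chain genes, and NRIP1 (−0.66, SE 0.20, adjusted p = 0.0377), a corepressor of nuclear receptors. Among 35 ERR target genes, 0 rose, 9 fell and 26 did not pass (0 and 9 adjusted over the list alone), with a median of −0.60 and a list adjusted p of 2.70e-05. Falls were seen for MDH1, a malate dehydrogenase (1893 ± 98.7 to 772 ± 277 CPM, adjusted p = 0.0159), and FABP3, the heart fatty acid binding protein (965 ± 170 to 516 ± 86.4 CPM, adjusted p = 0.0169). SLC25A20, the carnitine carrier (53.8 ± 4.13 to 35.5 ± 3.88 CPM, adjusted p = 0.0169), and ACADM, the medium-chain acyl-CoA dehydrogenase (879 ± 70.9 to 513 ± 63.0 CPM, adjusted p = 0.0171), fell as well. Of the 35 targets, 28 also belong to another metabolic list described here. Neither list passed with an estimated correlation (adjusted p = 0.675 with an estimated correlation for both). The regulators also failed without vehicle 1 (0.0520), doxorubicin 3 (0.0561) or doxorubicin 5 (0.160), with library size only (0.0671) and without the density trend (0.0962). With library size only the regulators had 3 members higher and 1 lower (median −0.04) and the targets 0 and 2 (median −0.25). Targets still passed camera in that fit (adjusted p = 5.51e-06), where all tested genes had a median of 0.378. The regulators had 0 and 3 without the density trend and 2 and 6 without doxorubicin 5. None of the 8 list members named as falling passed whichever library was left out, with adjusted p up to 0.156 for NRIP1 without vehicle 1. TFB2M, GABPA, NRIP1, FABP3, SLC25A20 and ACADM did not pass with library size only, nor GABPA and NRIP1 without the density trend, GABPA without a filter (0.0686) or NRIP1 without the length trend (0.207).

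**Figure D2:**
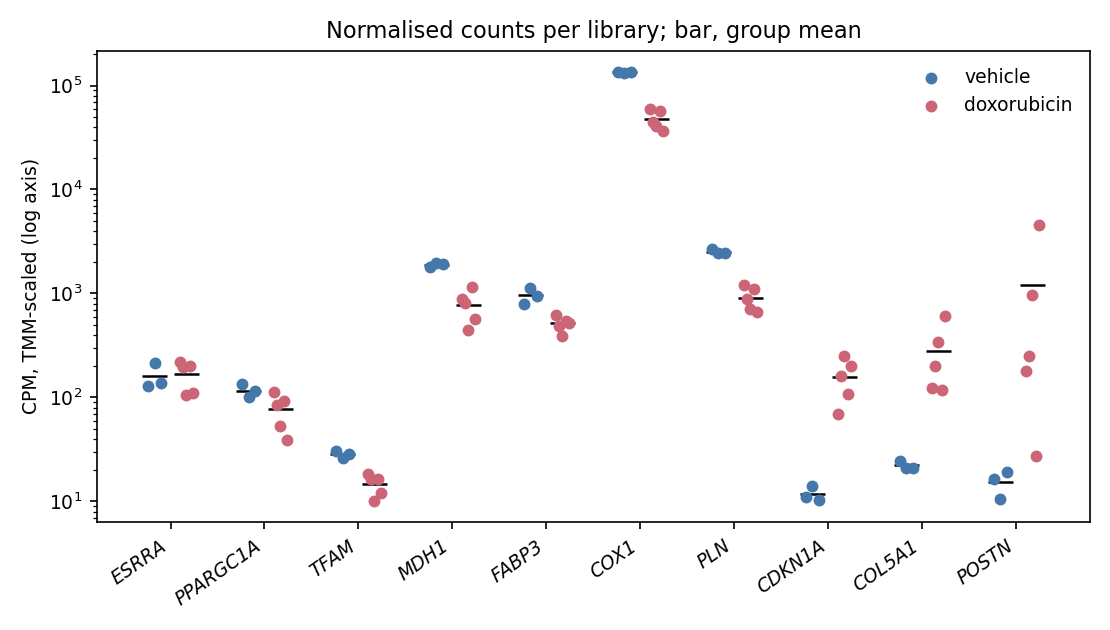
TMM-scaled CPM (log axis) of 10 genes in the 3 vehicle and 5 doxorubicin libraries, each point 1 library and each bar a group mean. ESRRA overlaps between the groups, TFAM, MDH1, FABP3, COX1 and PLN lie lower after doxorubicin, and CDKN1A, COL5A1 and POSTN lie higher.

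Respiratory chain subunits that passed as lower came from both genomes. They were most of those encoded in mitochondrial DNA and a minority of those encoded in the nucleus. Fold changes were negative for 12 of 13 tested subunits of mitochondrial DNA and for 55 of 68 of the nucleus. The mitochondrial DNA list had 0 members higher, 10 lower and 3 that did not pass (0 and 11 adjusted over the list alone). COX2, COX1, ND2 and ND3, subunits of cytochrome oxidase and of complex I, had log2 fold changes of −1.83 (SE 0.28), −1.48 (SE 0.26), −1.75 (SE 0.31) and −1.17 (SE 0.24). COX1 alone went from 11.4% ± 0.348 of all counts to 5.20% ± 0.967. All genes of mitochondrial DNA went from 25.3% ± 1.99 to 12.8% ± 2.83 (SD, n = 3 and n = 5; exact permutation p = 0.0357, the smallest this design allows; adjusted p = 0.0429 over 6 shares). Some of those shares were not planned, COX1 among them, which lies within the mitochondrial share. All the added shares had the smallest p, which lowers the adjusted p. Over the planned shares alone it lies above 0.05. With any 1 library left out the mitochondrial share kept the smallest p that design allows, which lies above 0.05. An unannotated nuclear locus that the deposited table describes as like COX1 took 2.70% of counts in vehicle and 1.65% after doxorubicin, so reads of COX1 can be split with it. Of 84 listed oxidative phosphorylation subunits encoded in the nucleus, 16 were not found under their symbols, most of them in complexes III and IV. Of the 68 tested, 2 rose, 15 fell and 51 did not pass (2 and 15 adjusted over the list alone), with a median of −0.43 and an adjusted p of 5.51e-05. Complex I had 2 higher, 9 lower and 26 not passing of 37 (2 and 10 adjusted over the list alone; median −0.38, adjusted p = 0.00313). Lower members included NDUFA5 (−0.89, SE 0.18), NDUFB9 (−0.98, SE 0.22) and NDUFS5 (−0.88, SE 0.20), and NDUFA3 was higher (1.39, SE 0.30). Complex II had 2 lower and 2 not passing of 4 (3 lower adjusted over the list alone; median −0.68, adjusted p = 0.0269), with SDHB at −1.15 (SE 0.27) and SDHC at −0.75 (SE 0.22). ATP synthase had 2 lower, ATP5O (−1.38, SE 0.24) and ATP5H (−1.31, SE 0.25), and 15 not passing of 17 (0 and 2 adjusted over the list alone; median −0.44, adjusted p = 0.00589). Complex IV with cytochrome c had 2 lower and 6 not passing of 8 (3 lower adjusted over the list alone; median −0.41) and was not called (adjusted p = 0.137). The other 8 of its 16 listed members were not found under their symbols, so the complex was tested only in part. No list of the 4 called passed with an estimated correlation (adjusted p = 0.706 with an estimated correlation for complex I, 0.675 for the mitochondrial DNA list, complex II and ATP synthase), nor did the nuclear subunits (adjusted p = 0.675 with an estimated correlation). Without vehicle 2, complex I (0.0972), complex II (0.0630) and ATP synthase (0.0609) were not called. Nor was complex II without doxorubicin 5 (0.0528). With library size only the nuclear subunits had 6 higher and 6 lower calls (median −0.08), complex I 4 and 3 (median −0.04), complex II 0 and 1, ATP synthase 0 and 2 (median −0.09) and the mitochondrial DNA list 0 and 7. Each of these lists still passed camera with library size only, with adjusted p from 6.27e-09 (mitochondrial DNA) to 0.0257 (complex II). Without the density trend the nuclear subunits had 1 higher and 24 lower, complex I 1 and 16 (median −0.63) and ATP synthase 0 and 4. COX1, COX2, ND2 and ATP5O passed whichever library was left out. The other named genes reached an adjusted p of up to 0.105 (SDHC without vehicle 2), and NDUFS5 and SDHC did not pass with library size only.

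A minority of the genes of fuel oxidation passed as lower, though most had negative fold changes. Negative were 29 of 33 fatty acid genes and 25 of 27 TCA cycle genes. Among ketone and branched-chain genes 21 of 22 were negative, and 12 of 15 in creatine and nucleotide exchange. Fatty acid uptake and oxidation had 0 genes higher, 12 lower and 21 not passing of 33 (0 and 15 adjusted over the list alone), with a median of −0.75 and an adjusted p of 2.18e-05. ACADL, the long-chain acyl-CoA dehydrogenase, fell by 1.37 on the log2 scale (SE 0.21). DECR1, a reductase needed for unsaturated fatty acids, fell by 0.89 (SE 0.19), and ACAA2, a thiolase, fell by 1.21 (SE 0.27). The TCA cycle and pyruvate entry had 0 higher, 8 lower and 19 not passing of 27 (0 and 9 adjusted over the list alone; median −0.65, adjusted p = 1.37e-05). MPC1 (−1.07, SE 0.20) and MPC2 (−0.93, SE 0.21), which form the mitochondrial pyruvate carrier, SUCLG2 (−1.02, SE 0.21), a subunit of succinyl-CoA ligase, and PDK1 (−1.07, SE 0.24) were among them. PDK1 fell like the others but inhibits pyruvate dehydrogenase, and the effect on its activity was not tested. Use of ketones and branched-chain amino acids had 0 higher, 8 lower and 14 not passing of 22 (1 and 9 adjusted over the list alone; median −0.62, adjusted p = 9.21e-05). Its lower members with the smallest p were DBT (−1.31, SE 0.25), the lactate and ketone carrier SLC16A1 (−0.83, SE 0.16), MUT (−0.83, SE 0.18) and HIBADH (−0.85, SE 0.20). Creatine and nucleotide exchange had 1 higher, 4 lower and 10 not passing of 15 (1 and 8 adjusted over the list alone; median −0.57, adjusted p = 0.0236). CKM (−1.15, SE 0.37), ADSL (−0.62, SE 0.16), AMPD3 (−0.82, SE 0.23) and VDAC2 (−0.72, SE 0.23) fell, while CKB, the brain-type creatine kinase, rose 7.09-fold (SE of log2 0.82). None of the 4 lists passed with an estimated correlation (adjusted p = 0.675 with an estimated correlation for each). Creatine and nucleotide exchange was not called without vehicle 2 (0.0609) and had 2 higher and 0 lower members with library size only (median −0.22). With that scaling fatty acid oxidation had 1 higher and 3 lower (median −0.40), the TCA cycle 0 and 7 (median −0.31) and ketone and branched-chain use 1 and 2 (median −0.27). Each of the 4 lists still passed camera with library size only, with adjusted p from 4.24e-06 (TCA cycle) to 0.0278 (creatine and nucleotide exchange). CKB was at 3.69-fold without doxorubicin 5. Among the genes named here ACADL alone passed whichever library was left out. The others lost their call without at least 1 vehicle library, with adjusted p up to 0.142 (CKM without vehicle 3). MUT, HIBADH, CKM, ADSL, AMPD3 and VDAC2 did not pass with library size only, nor AMPD3 and VDAC2 without the density trend. CKB (0.109), VDAC2 (0.0682) and CKM (0.0566) did not pass without a filter.

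Other mitochondrial groups split by direction. The mitochondrial ribosome and translation list had 2 higher, 12 lower and 27 not passing of 41 (3 and 18 adjusted over the list alone; median −0.40, adjusted p = 0.00387). The smallest p belonged to the ribosomal proteins MRPL1 (−0.96, SE 0.14), MRPS22 (−1.11, SE 0.19), MRPS10 (−0.69, SE 0.14) and MRPS35 (−0.84, SE 0.18). Mitochondrial dynamics, mitophagy and proteases had 0 higher, 8 lower and 20 not passing of 28 (0 and 11 adjusted over the list alone; median −0.37, adjusted p = 0.00113). Its lower members included DNM1L, which drives fission (−0.82, SE 0.14), OPA1 (−1.02, SE 0.18) and MFN1 (−0.69, SE 0.13), which drive fusion, and the protease subunit CLPX (−0.90, SE 0.16). The mitochondrial stress response, by contrast, had 8 higher, 0 lower and 11 not passing of 19 (9 and 0 adjusted over the list alone; median 0.75, adjusted p = 0.00387). SESN2, which restrains mTORC1, rose 4.28-fold (SE of log2 0.42), ATF5, a transcription factor of the stress response, 3.96-fold (SE of log2 0.47) and ALDH1L2, a mitochondrial folate enzyme, 1.56-fold (SE of log2 0.17). GDF15, a secreted stress signal, went from 0 to 2 reads in the vehicle libraries to 2 to 168 reads (adjusted p = 0.0227). No list here passed with an estimated correlation (adjusted p = 0.675 with an estimated correlation for each). The ribosome list was not called without vehicle 2 (0.0867) and had 6 higher and 2 lower members with library size only (median −0.04), where dynamics had 2 and 3 (median −0.02). The ribosome and dynamics lists still passed camera with library size only (adjusted p = 0.0338 and 0.00841). Without doxorubicin 5 the stress response median was 0.36 (adjusted p = 0.0349), and without the density trend 0.41. ATF5 was at 7.10-fold without vehicle 2. The log2 fold change of GDF15 went from 6.15 to 9.13 without vehicle 3, but with 0 to 2 vehicle reads its size is not well determined. MRPL1, MRPS22, DNM1L, OPA1 and CLPX passed whichever library was left out. The others reached an adjusted p of up to 0.110 (ALDH1L2 without vehicle 3). MRPS10, MRPS35 and MFN1 did not pass with library size only, nor ALDH1L2 without the density trend.

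Targets of p53 moved both ways. Of 29, 12 rose, 7 fell and 10 did not pass (14 and 9 adjusted over the list alone), with a median of 0.44 and an adjusted p of 0.0294. Besides CDKN1A (chromosome 7, 32354776 to 32363771; log2 fold change 3.74, SE 0.44, adjusted p = 0.00437), BBC3, a trigger of apoptosis, rose 7.32-fold (SE of log2 0.43), PHLDA3, an inhibitor of AKT, 7.15-fold (SE of log2 0.49) and AEN, a nuclease of apoptosis, 2.83-fold (SE of log2 0.24). The cell cycle and proliferation list had 19 higher, 1 lower and 19 not passing of 39 (20 and 3 adjusted over the list alone; median 1.15, adjusted p = 9.21e-05). MKI67, a marker of dividing cells, rose 3.93-fold (SE of log2 0.30), and TYMS, which makes thymidylate, 9.21-fold (SE of log2 0.50). The replication helicase subunits MCM2 and MCM5 rose 4.07-fold (SE of log2 0.35) and 3.10-fold (SE of log2 0.30). Anthracycline targets and transport had 9 higher, 1 lower and 17 not passing of 27 (9 and 1 adjusted over the list alone; median 0.53, adjusted p = 0.0294). RARG, the retinoic acid receptor gamma gene, was at 2.23-fold (SE of log2 0.16), RAC2 and CYBA, parts of the NADPH oxidase, at 2.47-fold (SE of log2 0.27) and 5.42-fold (SE of log2 0.64), and the drug exporter ABCC3 at 3.72-fold (SE of log2 0.47). The deposited table annotates the RARG locus as a lncRNA. TOP2B, the topoisomerase that anthracyclines poison in the heart (chromosome 13, 12507738 to 12575042, protein-coding), was lower at 93.4 ± 8.54 CPM against 130 ± 7.31 CPM (log2 fold change −0.47, SE 0.14, adjusted p = 0.0351). Its call ended without any 1 of vehicle 1, 2 and 3 and doxorubicin 2, 3 and 4 (adjusted p 0.0562 to 0.125), and with library size only, without the density trend or without a filter. With an estimated correlation the 3 lists did not pass (adjusted p = 0.675 with an estimated correlation for each). The p53 targets were not called without vehicle 2 (0.0595) or doxorubicin 5 (0.0534) or with cameraPR (0.0984). Anthracycline targets were not called without vehicle 2 (0.0867) or with the CPM filter (0.0582). With library size only the p53 targets had 17 higher and 3 lower (median 0.81) and anthracycline targets 12 and 0 (median 0.89). Anthracycline targets had 5 and 0 without the density trend, and CYBA was at 3.60-fold without doxorubicin 5. CDKN1A, BBC3, AEN, PHLDA3, MKI67, TYMS, MCM2 and RARG passed whichever library was left out. MCM5, RAC2, ABCC3 and CYBA did not without 1 or more vehicle libraries (adjusted p up to 0.103, CYBA without vehicle 1), nor did CYBA without a filter (0.0658).

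Matrix genes rose more than any other gene list tested. The collagen and extracellular matrix list had 31 higher, 0 lower and 9 not passing of 40 (36 and 0 adjusted over the list alone), a median of 2.87 with 1 gene at 0 reads in vehicle set to its bound or not, and a median of 1.86 without doxorubicin 5. COL4A2, of basement membranes, rose from 225 ± 12.2 to 734 ± 127 CPM (adjusted p = 0.00437), and COL5A1, which starts collagen fibrils, from 22.3 ± 2.09 to 278 ± 202 CPM (adjusted p = 0.00715). COL12A1, a fibril-associated collagen, rose from 13.6 ± 2.76 to 213 ± 163 CPM (adjusted p = 0.00907), and LOXL1, which crosslinks elastin, from 6.42 ± 1.14 to 88.3 ± 48.0 CPM (adjusted p = 0.00525). TGF-beta signalling had 11 higher, 2 lower and 15 not passing of 28 (13 and 2 adjusted over the list alone; median 0.73, adjusted p = 0.0109). The latent TGF-beta binding proteins LTBP2 and LTBP3 rose 30.8-fold (SE of log2 0.80) and 6.32-fold (SE of log2 0.58) and BMP4 2.35-fold (SE of log2 0.21). SMAD4, the shared mediator of the pathway, fell by 0.70 on the log2 scale (SE 0.12). The fetal and stress gene programme had 7 higher, 0 lower and 18 not passing of 25 (8 and 0 adjusted over the list alone; median 1.06, adjusted p = 0.000789). Higher members included the chaperone CRYAB at 2.18-fold (SE of log2 0.21), NES, an intermediate filament, at 8.84-fold (SE of log2 0.68) and CTGF, a matricellular protein, at 8.97-fold (SE of log2 0.69). NPPB, the B-type natriuretic peptide gene (chromosome 6, 71930374 to 71931843), had 0 to 21 reads in vehicle and 204 to 20435 reads after doxorubicin (log2 fold change 9.34, SE 1.86, adjusted p = 0.0116). NPPA, the atrial natriuretic peptide gene (chromosome 6, 71919557 to 71921345), was at 7.86 ± 2.58 and 24.3 ± 21.3 CPM (log2 fold change 1.63, SE 0.73, adjusted p = 0.123), and at 2-fold without doxorubicin 3 against 3.10-fold with all libraries. MYH7, the slow myosin heavy chain gene (chromosome 7, 75650841 to 75672908), was at 33631 ± 2744 and 26357 ± 8518 CPM (log2 fold change −0.35, SE 0.32, adjusted p = 0.443). The 3 lists did not pass with an estimated correlation (adjusted p = 0.675 with an estimated correlation for each). TGF-beta signalling was not called without vehicle 2 (0.0555). Fetal and stress genes had 16 higher and 0 lower with library size only. NES was at 5.72-fold without doxorubicin 3, and the log2 fold change of NPPB ran from 8.68 without doxorubicin 3 to 11.33 without vehicle 2. COL4A2, COL5A1, LOXL1, LTBP2, BMP4 and SMAD4 passed whichever library was left out. COL12A1, LTBP3, CRYAB, NES, CTGF and NPPB did not without 1 or more vehicle libraries (adjusted p up to 0.0688, LTBP3 without vehicle 1). SMAD4 did not pass with library size only, nor NPPB with voom.

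The 10 higher genes with the smallest p were led by IGSF23, of the immunoglobulin superfamily (chromosome 6, 51133074 to 51150820). It had 0 reads in every vehicle library and 285 to 505 reads in every doxorubicin library (adjusted p = 0.000507). PALD1 (3.33-fold), MAFK, a small MAF transcription factor (3.24-fold), C1QTNF6, a secreted C1q-like protein (14.3-fold), and TTYH3 (3.75-fold) came next. RAB40B, a small GTPase (3.40-fold), GAS8, a ciliary protein (3.29-fold), MBOAT2, a phospholipid acyltransferase (2.73-fold), CDKN1A and SIPA1, which inactivates RAP1 (2.60-fold), completed the 10. Adjusted p was 0.00329 for PALD1 and 0.00437 for the others. The log2 SE of these 9 ran from 0.16 to 0.44. The 10 lower genes were led by MARC1, a molybdenum enzyme of the outer mitochondrial membrane (chromosome 10, 10190759 to 10264467; 66.9 ± 3.01 to 17.0 ± 1.96 CPM, adjusted p = 0.000507), and GKAP1, an anchor of cGMP-dependent kinase (log2 fold change −1.94, SE 0.15, adjusted p = 0.000696). The next 8 are listed by size of change and not by p. RSPO3, a WNT enhancer (−4.14), KLHL32 (−2.27), TECRL, in which variants cause inherited arrhythmia (−1.72), and GPALPP1 (−1.25) changed most among them. The others were AGTR1, the main angiotensin receptor (−1.23), CRYZ, a quinone reductase (−1.21), USP15, a deubiquitinase (−1.17), and VPS37A, of the ESCRT machinery (−1.12). These 8 had adjusted p of 0.00437 and SE from 0.13 to 0.47. All 20 are annotated as protein-coding, and the values of the 2 groups did not overlap, as the rule required.

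Markers of several cell types moved with treatment. Macrophage and monocyte markers had 7 higher, 0 lower and 12 not passing of 19 (7 and 0 adjusted over the list alone; median 1.25, adjusted p = 0.00113). They included the complement genes C1QC (4.51-fold, SE of log2 0.38) and C1QB (3.54-fold, SE of log2 0.39), the growth factor receptor CSF1R (2.64-fold, SE of log2 0.30) and CD68 (2.67-fold, SE of log2 0.33). T and NK cell markers had 8 higher, 0 lower and 8 not passing of 16 (12 and 0 adjusted over the list alone; median 1.60, adjusted p = 0.000183). They included CD8A (3.79-fold, SE of log2 0.39), NKG7 (3.16-fold, SE of log2 0.35), CD3E (2.36-fold, SE of log2 0.31) and KLRK1 (3.19-fold, SE of log2 0.45). Myofibroblast markers had 5 higher, 0 lower and 3 not passing of 8 (6 and 0 adjusted over the list alone; median 3.31, adjusted p = 0.00429). They included POSTN (77.5-fold, SE of log2 1.70), CTHRC1 (0.848 ± 0.0745 to 41.3 ± 55.2 CPM), TNC (25.4-fold, SE of log2 1.33) and MEOX1 (2.84-fold, SE of log2 0.29), and 4 of the 8 are also in the matrix list. Doxorubicin 5 carried much of this, with POSTN at 23.3-fold, CTHRC1 at 21.1-fold, TNC at 8.80-fold and the list median at 2.30 without it. TNC was at 39.2-fold without vehicle 1. Immediate early genes, which respond to tissue handling as well as to stress, had 5 higher, 0 lower and 15 not passing of 20 (6 and 0 adjusted over the list alone; median 0.64, adjusted p = 0.00329). Among them were IER2 (3.04-fold, SE of log2 0.32), JUNB (5.21-fold, SE of log2 0.48), NR4A2 (2.25-fold, SE of log2 0.26) and NR4A3 (4.34-fold, SE of log2 0.55). Cardiomyocyte markers had 0 higher, 3 lower and 10 not passing of 13 (0 and 2 adjusted over the list alone; median −0.43, adjusted p = 0.0466). These were PLN, which restrains the calcium pump of the sarcoplasmic reticulum (−1.48, SE 0.24), RYR2, its calcium release channel (−1.82, SE 0.53), and CKM. Adipocyte markers had 0 higher, 2 lower and 8 not passing of 10 (0 and 2 adjusted over the list alone; median −0.93, adjusted p = 0.00387). The 2 were ADIPOQ, an adipocyte hormone (30 to 265 reads in vehicle and 0 to 4 reads after doxorubicin), and FABP4 (−1.92, SE 0.42). None of the 6 passed with an estimated correlation (adjusted p = 0.675 with an estimated correlation for each). Cardiomyocyte markers were not called without vehicle 2 (0.129), doxorubicin 3 (0.101) or doxorubicin 5 (0.0685), with the CPM filter (0.0582) or with cameraPR (0.0984), and had 2 members higher and 1 lower with library size only (median −0.09). With library size only the cardiomyocyte markers still passed camera (adjusted p = 0.031). Without the density trend T and NK cell markers had 4 higher, adipocyte markers 4 lower and macrophage markers a median of 0.72. With library size only 12 immediate early genes and 12 T and NK cell markers were higher, and adipocyte markers had a median of −0.60. PLN and ADIPOQ passed whichever library was left out, but ADIPOQ did not with voom (0.0581), and its log2 fold change went from −6.15 to −4.75 without vehicle 3. No other gene named here did, with adjusted p up to 0.142 (CKM without vehicle 3). RYR2 and CKM did not pass with library size only, nor CD68 and KLRK1 without the density trend. Without a filter POSTN (0.0973), CTHRC1 (0.0983), TNC (0.115), NR4A3 (0.0588), RYR2 (0.0547) and CKM (0.0566) did not pass, nor did CTHRC1 with voom (0.123).

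**Figure D3:**
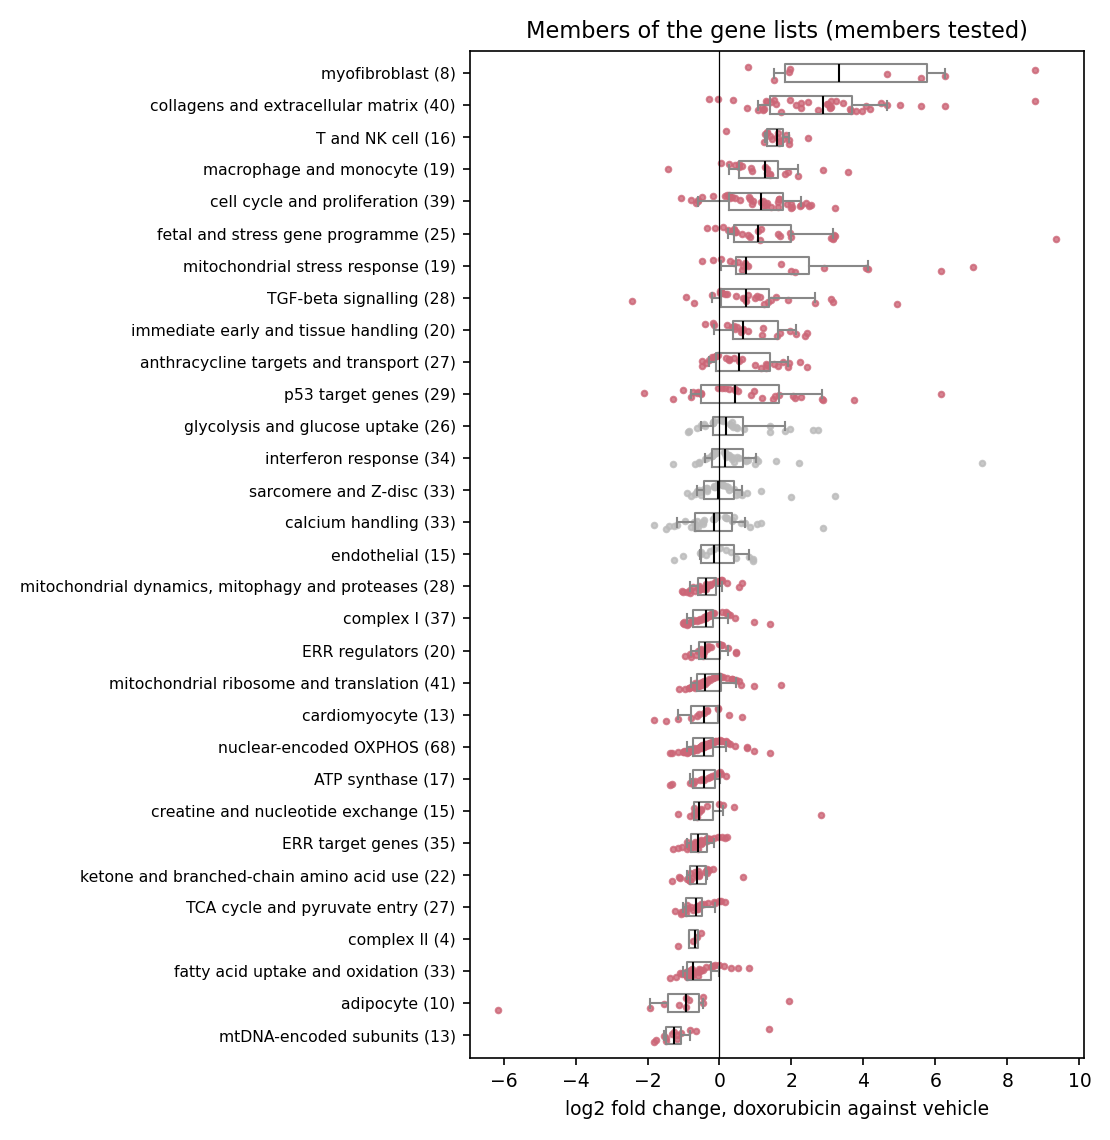
Log2 fold changes of the members of 31 lists, each point 1 gene, with the number of tested members after the name. Boxes show the median and quartiles and whiskers the 10th to 90th percentiles; red lists passed camera at the preset correlation and grey lists did not. The matrix, myofibroblast and lymphocyte lists lie above 0 and the fuel oxidation and respiratory chain lists below 0.

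Lists of the contractile apparatus and of general cell upkeep did not pass. Sarcomere and Z-disc genes had 1 higher, 0 lower and 32 not passing of 33 (0 and 0 adjusted over the list alone; adjusted p = 0.792), with a median of −0.05, a mean of 0.10 and a median of 0.30 with library size only. Cytosolic ribosomal proteins had 1 higher and 57 not passing of 58 (0 and 0 adjusted over the list alone; adjusted p = 0.773). Counts for the other gene lists, as higher, lower and tested with the counts adjusted over the list alone in brackets, were 3, 10 and 33 for calcium handling (5 and 10; adjusted p = 0.0920). Ion channels and adrenergic signalling had 0, 4 and 32 (0 and 2; adjusted p = 0.0564). The counts were 3, 2 and 26 for glycolysis and glucose uptake (3 and 2; adjusted p = 0.797). They were 5, 2 and 31 for antioxidant defence (5 and 2; adjusted p = 0.938), 1, 4 and 23 for iron handling and ferroptosis (3 and 6; adjusted p = 0.184), and 1, 1 and 30 for DNA damage repair (0 and 1; adjusted p = 0.501). For apoptosis and necroptosis they were 8, 3 and 27 (9 and 4; adjusted p = 0.216). For heat shock and protein folding they were 3, 3 and 32 (2 and 0; adjusted p = 0.908), for the ubiquitin-proteasome system and autophagy 4, 4 and 36 (4 and 4; adjusted p = 0.299), and for glucocorticoid-induced genes 0, 3 and 17 (0 and 3; adjusted p = 0.0920). Hypoxia and angiogenesis had 3, 3 and 31 (3 and 3; adjusted p = 0.908), the circadian clock 2, 2 and 19 (2 and 2; adjusted p = 0.922), and inflammatory cytokines and NF-kB 8, 6 and 34 (12 and 6; adjusted p = 0.216). The interferon response had 3, 3 and 34 (3 and 3; adjusted p = 0.701), and antigen presentation and complement 6, 1 and 32 (6 and 1; adjusted p = 0.0765). Some of these passed in other fits. Ion channels passed with library size only (adjusted p = 0.0393, median 0.15) and without any 1 of vehicle 3 and doxorubicin 1, 2 and 4 (lowest 0.0271). Their median of 0.15 lay below that of all tested genes in the same fit (0.378). Antigen presentation passed with cameraPR (0.0338) and without vehicle 3, doxorubicin 1 or doxorubicin 2 (lowest 0.0244). Glucocorticoid-induced genes passed without vehicle 1 or doxorubicin 1 (lowest 0.0244), cytosolic ribosomal proteins without vehicle 1 or doxorubicin 5 (lowest 0.0368), and complex IV without vehicle 1 (0.0398). With library size only most counts moved up: calcium handling had 8 higher and 1 lower (median 0.21), iron handling 4 and 1 and glucocorticoid-induced genes 2 and 0, each the opposite balance. Heat shock then had 10 and 0, ubiquitin-proteasome 8 and 0, interferon 11 and 1, inflammatory genes 15 and 4, apoptosis 13 and 2, glycolysis 9 and 1, and hypoxia 8 and 1. Antigen presentation had 12 and 1, antioxidant defence 7 and 1, sarcomere genes 7 and 0, cytosolic ribosomal proteins 6 and 0, the clock 5 and 1, DNA repair 4 and 0, ion channels 2 and 2, and complex IV 1 and 0. Apoptosis had 5 and 5 and ubiquitin-proteasome 3 and 7 without the density trend. Without doxorubicin 5, cytosolic ribosomal proteins had 2 and 12, ubiquitin-proteasome 5 and 9, hypoxia 9 and 4, heat shock 6 and 6, glycolysis 6 and 2 and ion channels 1 and 8. By fry, 5 of the 58 lists moved one way: mitochondrial DNA (adjusted p = 0.0446), iron handling (0.0368), anthracycline targets (0.0367), the fetal programme (0.0451) and immediate early genes (0.0446). With an estimated correlation 0 of 58 lists passed in edgeR's camera. There 1 list, anthracycline targets and transport, had an unadjusted p under 0.05 (0.0301). The preranked variant, cameraPR, called 20 gene lists and 5 cell type lists.

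Other marker lists did not pass either. Endothelial markers had 2 higher and 1 lower of 15 (3 and 1 adjusted over the list alone; median −0.14, adjusted p = 0.908), fibroblast markers 3 and 1 of 14 (6 and 1; median 0.34, adjusted p = 0.299), and pericyte and smooth muscle markers 4 and 1 of 14 (5 and 1; median 0.74, adjusted p = 0.168). Atrial cardiomyocyte markers had 2 and 1 of 8 (3 and 1; adjusted p = 0.496), ventricular 2 and 1 of 7 (2 and 1; adjusted p = 0.947), conduction system 1 and 1 of 7 (1 and 1; adjusted p = 0.922), and endocardial and lymphatic endothelial 1 and 1 of 9 (0 and 0; adjusted p = 0.661). Neutrophil markers had 0 and 1 of 6 (0 and 1; adjusted p = 0.908), B and plasma cell markers 0 and 0 of 5 (0 and 0; adjusted p = 0.644), mast cell markers 0 and 0 of 5 (0 and 0; adjusted p = 0.775), and erythroid and platelet markers 1 and 0 of 5 (1 and 0; adjusted p = 0.922). Neuronal and Schwann cell markers had 1 and 3 of 9 (2 and 4; median −1.35, adjusted p = 0.391), mesothelial and epicardial markers 1 and 0 of 5 (1 and 0; adjusted p = 0.284), and skeletal muscle markers 2 and 1 of 7 (2 and 3; adjusted p = 0.938). Pericyte and smooth muscle markers passed without vehicle 1 (adjusted p = 0.0405). With 1 library left out the endothelial median ran from −0.30 to −0.001, the fibroblast median from 0.20 to 0.43 and the neuronal median from −1.62 to −0.86. Fibroblast markers had 6 higher and 0 lower with library size only, endothelial markers 4 and 1 and neuronal markers 3 and 0. Median and mean differed in sign for ventricular markers (−0.16 and 0.11). For skeletal muscle markers the median was −0.13 while the test pointed up, and for neutrophil markers it was 0.48 while the test pointed down. The share of haemoglobin reads was 0.00526% ± 0.00265 in vehicle and 0.00341% ± 0.00335 after doxorubicin (exact permutation p = 0.393).

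Higher and lower calls lay in different genomic surroundings. With the genes sorted into 5 groups by the number of protein-coding genes within 500 kb, higher calls numbered 177, 223, 316, 542 and 718 from the sparsest to the densest group, and lower calls 516, 487, 393, 181 and 74. Fold change and gene density correlated across 14682 genes, which are not independent replicates, with a Spearman rho of 0.286. Within libraries the trend was taken on the deviation of each gene from its mean over the 8 libraries. It was negative in each vehicle library (rho −0.352 to −0.136) and positive in each doxorubicin library (0.144 to 0.221). Such deviations cancel over the libraries, so a group difference gives the groups opposite signs on average. The signs are therefore not evidence apart from the correlation of the fold changes. The 20 most abundant genes took 34.7% ± 0.787 of counts in vehicle and 22.9% ± 3.92 after doxorubicin (exact permutation p = 0.0357, adjusted p = 0.0429), and unannotated loci 2.94% ± 0.120 and 1.94% ± 0.507 (exact permutation p = 0.0357, adjusted p = 0.0429). The share of unannotated loci was not planned. Over the planned shares alone the adjusted p of the 20 most abundant genes lies above 0.05.

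**Figure D4:**
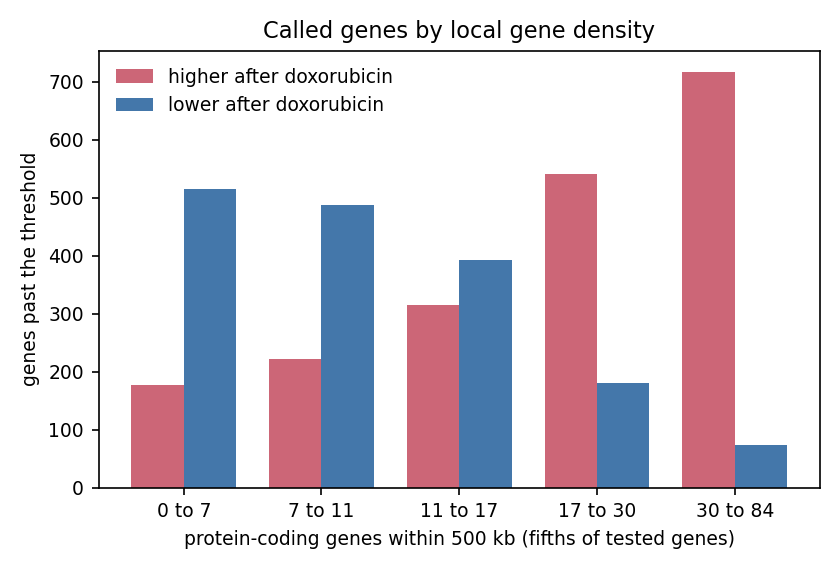
Number of genes past the threshold (vertical axis) in 5 equal groups of tested genes by the number of protein-coding genes within 500 kb (horizontal axis), as red bars for genes higher and blue bars for genes lower after doxorubicin. Higher calls go from 177 to 718 and lower calls from 516 to 74 between the sparsest and the densest group.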

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

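Tests chosen only after the result was seen were those on transcript length, on library preparation, on the share of cardiomyocytes, on loci read in vehicle alone, on splits by their number of vehicle libraries and on the calls that ended without the density trend. Matching on level in the tests of spread was also chosen after unmatched values were seen, so both ranges are printed. The test of the density trend was written before its value was known, but was moved from the density pattern to the number of calls afterwards, with its wording unchanged.

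Among 63 values tested, 5 stood far from the rest of their group by Dixon's test, which flags about 1 in 20 groups by chance. Doxorubicin 5 had a second principal component of 55.97, with −15.19 the nearest of its group, and a trend with gene length of rho −0.282, with 0.00986 the nearest. Doxorubicin 1 had a haemoglobin share of 0.009225%, with 0.00335% the nearest. Doxorubicin 3 had a mean log2 CPM of 4.884 over mitochondrial ribosome and translation genes, with 5.288 the nearest. Doxorubicin 5 also had 1.873 log2 CPM of KLHL32, with 2.932 the nearest.

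The number of called genes and their gene density were weighed together. Of the 56 splits of the libraries, 1 gave as many calls as the real split, namely the real split itself (3714), and the highest other, with 1586, set doxorubicin 2, 3 and 5 against the rest, which points to a structure among the samples. Of all calls, 68.8% stood in the same direction after each library's density trend was removed, which argues against that trend as the whole cause. For the 1157 calls that ended, the median fold change in their own direction went from 0.786 to 0.501 on the log2 scale, 63.8% of its size, and the median SE from 0.216 to 0.205, so the smaller fold ended them and whether the trend made them cannot be told apart.

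The link to gene density was not explained by the span or length of genes. Given genomic span, its rho was 0.227 (0.184 to 0.253 over 500 chromosome bootstraps), and rho with transcript length was −0.092 (−0.112 to −0.0678). Every doxorubicin library had a higher trend than every vehicle library, by at least 0.28, with trends measured against each gene's mean over the 8 libraries. A library preparation or run that differed between the groups cannot be told apart from treatment here, because the labels give no batch, and GC content was not tested. Treatment, which the design names, also stays open.

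IGSF23 belongs to 23 loci read in every library of 1 group and with at most 2 reads in every library of the other, 18 read after doxorubicin and 5 read in vehicle. They include TREM2, a macrophage receptor, EMID1 and KIF12, and on the vehicle side PON3, a paraoxonase, and the lncRNA LOC102159416. The other split with the most of them had 9, which argues against differences between samples unrelated to group. Levels of the 18 varied by a median of 70.2% (CV) over the doxorubicin libraries. Random sets of other higher calls of like level had 31.4 to 57.4% (18.5 to 43.3% unmatched). A difference of stock carried evenly by 1 group predicts even levels, but this test cannot decide on it. The other calls had passed a test that favours small spread, while the 18 were chosen by their near absence in vehicle. IGSF23 itself had a CV of 20.1%. For the 5 vehicle loci the median CV was 31.8% against 12.4 to 38.3% (4.6 to 19.4% unmatched). A stock difference and treatment cannot be told apart for either set of loci.

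Lower metabolic lists were not called biological. In 16 of 56 splits at least as many gene lists passed as the 20 of the real split (highest other 29). That count takes all 38 gene lists in both directions, so it does not test the lower metabolic lists. With 1 vehicle library in the group of 3, 5 of 30 splits reached it (highest 26), and with 2, 7 of 15 did (highest 28). Splits that keep vehicle libraries together hold part of the treatment difference. Chance can therefore not be excluded for the count of lists, which tests no single list, and treatment stays open too. A lower share of cardiomyocytes goes with the cardiomyocyte markers, 11 of 13 of which had negative fold changes (median −0.43, adjusted p = 0.0466; 11 of the 13 are also in the sarcomere or calcium lists), near the −0.43 of nuclear oxidative phosphorylation. Those markers did not pass in camera with an estimated correlation (adjusted p = 0.675) or without vehicle 2 (0.129). With library size only their median was −0.09, and that of nuclear oxidative phosphorylation −0.08. All tested genes then had a median of 0.378, and both lists still passed camera (adjusted p = 0.031 and 0.000165). Sarcomere and Z-disc genes had a median 0.541 above that of 141 metabolic genes (permutation p = 4.0e-05 over genes, which are not independent). Those 141 came from the mitochondrial DNA, nuclear oxidative phosphorylation, TCA and fatty acid lists together. That difference went the way predicted if a lower share was not the whole cause. It cannot decide, because 7 of the 25 fetal and stress genes, a list that rose (median 1.06), are also in the sarcomere list. A rise of such genes could offset a loss of cardiomyocytes. Such a rise was largely not shown for them, since 1 of the 33 sarcomere and Z-disc genes passed as higher and 0 as lower. Endothelial markers had a median of −0.14 and myofibroblast markers of 3.31, which does not tell a loss of cardiomyocytes from growth of other cells. A lower share of cardiomyocytes therefore stays open. The density trend was argued against by the 128 of the 141 genes that lie in the nucleus, with a median of −0.548 before and −0.684 after its removal.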

How the results depend on the processing

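Removal of the density and length trends, the fit of 6 libraries without a block and list members without doxorubicin 5 were tests added after the data were seen. No call shared with any alternative turned direction. Calls numbered 3698 with RLE, 2902 without a filter, 4845 with DESeq2 and 4211 without the length trend, against 3714. They moved to 8051 with voom (4030 higher, 4021 lower), and the cause was not tested. With library size only they moved to 4093 higher and 499 lower. That fit leaves out the TMM factors, which ran from 0.839 to 0.874 in vehicle and from 1.05 to 1.18 after doxorubicin. Their omission moved the median log2 fold change of all tested genes by 0.357. A 2-fold minimum left 1885 (1389 higher, 496 lower) by its construction. With 1 library left out, which leaves fewer samples, calls ran from 649 (without vehicle 1) to 4737 (without doxorubicin 5), higher calls from 334 to 2472 and lower calls from 315 to 2265. Gene lists past the threshold ran from 12 to 23 and cell type lists from 5 to 7. An estimated correlation left 0 gene lists and 0 cell type lists, and fry 4 and 1. ERR targets (median −0.598) had adjusted p of 0.675 with an estimated correlation and 0.109 with fry, and nuclear oxidative phosphorylation subunits (median −0.433) 0.675 and 0.168. Those tests differ in allowing for correlation between genes or in their null. The ESRRA log2 fold change ran from −0.084 to 0.323 with 1 library left out and was −0.319 without the density trend, and PPARA was 0.026 with library size only, none past the test. TOP2B lost its call in several fits (adjusted p 0.0562 to 0.566), and NPPB without vehicle 1 (0.0542) or vehicle 3 (0.0581) and with voom. NPPA passed with DESeq2 (0.0325) and without doxorubicin 2 (0.0440) and was at 2-fold without doxorubicin 3, and PPARGC1A with voom (0.0286). With the replicate block on 6 libraries 3646 genes passed (4101 without a block), and the ERR regulators were not called (adjusted p = 0.126), while pericyte and smooth muscle markers were (0.0237). Cell cycle genes then had 10 higher and 1 lower (median 0.87) and T and NK cell markers 3 higher, in a fit of fewer libraries. The block ended the calls of TOP2B, GABPA, ALDH1L2, CKM, CD3E, KLRK1, NR4A3 and NFIL3, and the 6 libraries without it those of GABPA, KLRK1, NFIL3, PDGFRA and LUM. Samples with the same number had correlations of 0.0425, 0.002 and −0.0031, and from the vehicle side none correlated best with its own number, while from the doxorubicin side doxorubicin 1 alone did, so the numbers were not taken to pair the samples.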

Other observations

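Further genes passed in lists that did not. The lists in this paragraph and the next were picked by hand, and other lists that did not pass got no named genes. Within each, genes were taken by smallest p as above. In calcium handling, CACNA1G, a T-type calcium channel, rose 7.38-fold (SE of log2 0.55, adjusted p = 0.00974), while ASPH (−0.69, SE 0.13, adjusted p = 0.0105) and MCU, the mitochondrial calcium uniporter (−0.60, SE 0.13, adjusted p = 0.0136), were lower. In apoptosis, BAK1, which permeabilizes mitochondria, rose 2.43-fold (SE of log2 0.24, adjusted p = 0.00882). BIRC3, an inhibitor of apoptosis, and DIABLO, which antagonizes such inhibitors, both fell, by 1.07 (SE 0.15, adjusted p = 0.00525) and 0.93 (SE 0.15, adjusted p = 0.00674) on the log2 scale. Among inflammatory genes the chemokines CCL4 and CCL5 rose 5.38-fold (SE of log2 0.43, adjusted p = 0.00818) and 7.94-fold (SE of log2 0.56, adjusted p = 0.00922), and RELA, an NF-kB subunit, 1.72-fold (SE of log2 0.16, adjusted p = 0.0113). VCAM1, an adhesion molecule of the vessel wall, fell by 0.96 (SE 0.15, adjusted p = 0.00622). BIRC3, DIABLO, VCAM1 and CCL4 passed whichever library was left out. The others did not without 1 or more vehicle libraries (adjusted p up to 0.0632, MCU without vehicle 3), ASPH and MCU did not pass with library size only, ASPH did not without the length trend (0.0530), and RELA did not without the density trend.

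Clock, vessel and fibroblast genes moved both ways. NR1D2, a repressor of the clock, went from 153 ± 24.6 to 65.1 ± 12.1 CPM (adjusted p = 0.00598), and its opponent RORA fell by 1.04 on the log2 scale (SE 0.24, adjusted p = 0.0153). NPAS2, a partner of BMAL1, rose 2.70-fold (SE of log2 0.35, adjusted p = 0.0188) and NFIL3 1.53-fold (SE of log2 0.18, adjusted p = 0.0327). Times of sampling are not given in the sources used here. Among endothelial markers SOX18 and EGFL7 each rose 1.91-fold (SE of log2 0.16 and 0.20, adjusted p = 0.00715 and 0.0127), and EMCN, a sialomucin, fell by 1.27 (SE 0.23, adjusted p = 0.00832). Among fibroblast markers COL1A1 went from 119 ± 22.2 to 2153 ± 2552 CPM (adjusted p = 0.0165), COL3A1 from 451 ± 50.5 to 3604 ± 4450 CPM (adjusted p = 0.0343), and LUM rose 2.47-fold (SE of log2 0.42, adjusted p = 0.0472). Without doxorubicin 5, COL1A1 was at 8.73-fold and COL3A1 at 3.64-fold. PDGFRA, the receptor of resident fibroblasts, fell by 1.13 (SE 0.33, adjusted p = 0.0355). NR1D2, SOX18 and EMCN alone passed whichever library was left out, the others reaching an adjusted p of up to 0.145 (LUM without vehicle 1). RORA and PDGFRA did not pass with library size only, nor PDGFRA without the density trend or the length trend (0.0558), and COL3A1 (0.0773) and LUM (0.0569) did not without a filter.

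Genes in this paragraph were chosen after the values were seen. SFRP2, a secreted WNT modulator of fibroblasts, had 0, 0 and 1 reads in vehicle and 228, 626, 2255, 0 and 2807 reads in doxorubicin 1 to 5. ACSM5, a mitochondrial acyl-CoA synthetase, had 632, 684 and 588 reads in vehicle and 491, 2, 313, 0 and 0 reads after doxorubicin. ENO2, the neuronal enolase, had 7, 2 and 3 reads in vehicle and 9, 11, 11, 2 and 1544 reads after doxorubicin. The lncRNA LOC102159416 (chromosome 10, 10145763 to 10153615) had 60, 131 and 110 reads in vehicle and 0 in every doxorubicin library, and lies near MARC1 (10190759 to 10264467), which was lower as well.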
